A study of Rattus norvegicus with 32 samples.

How the data were processed

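RNA from brainstem and hypothalamus was isolated with the Direct-zol kit and made into mRNA libraries with PrepX reagents on an Apollo 324 instrument, and the libraries were sequenced on an Illumina NextSeq instrument, per the labels' protocols. The 32 libraries fell into 8 groups of 4 by tissue, operation (sham or total bilateral adrenalectomy, ADREX) and exposure (filtered air, or ozone at 0.8 ppm, for 4 hours). Groups and replicate numbers were taken from the sample labels. Each of the 16 numbers occurs once in each tissue, and no source used here states whether a shared number marks an animal.

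The values are a signal, namely normalized read counts per gene, which the authors deposited as a table of 22587 genes by 32 libraries. Partek, DESeq2 and the rat genome build rn6 are named, without roles or versions, per the submitters' processing notes. The aligner and the gene annotation are not given in the sources used here. The only gene table in hand belongs to another assembly, GRCr8, so it was used for names and no coordinates are given. In each deposited column the values were whole multiples of a single step, between 0.623 and 1.25, as counts divided by the size factor of the library would be. Dividing by the step gave whole reads for 100% of values, within 0.001 of a whole number. The recovered totals were 6.44 to 12.4 M reads per library. Of these genes, 450 had 0 reads in every library, 5712 symbols were provisional, and no entry lacked a gene. Genes that share reads with a near-identical copy are uncertain, because the counting of such reads is not given in the sources used here.

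For the main tests the deposited values were taken as log2(value + 1), genes with a mean under 10 over the libraries of the fit were left out, and limma 3.58.1 was run in R 4.3.3 with a mean-dependent prior variance and Benjamini-Hochberg adjustment within each contrast. Adjusted p under 0.05 was a call. Each tissue was fitted on its 16 libraries with 4 group means, for ozone against air in sham and in ADREX rats, ADREX against sham in air and in ozone, and the interaction of both. Contrasts between tissues used all 32 libraries and 8 group means. Fold changes on this scale understate the change of low genes. Intervals of a log2 change, where used, are 95% intervals from limma's t quantiles.

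There were 30 gene lists fixed beforehand. They were the glucocorticoid-responsive genes, immediate early genes, neuropeptides and stress-axis genes, catecholamine synthesis, transport and receptors, HIF target genes, NRF2 antioxidant genes, inflammatory and acute-phase genes, interferon-responsive and antigen-presentation genes, circadian clock genes, heat-shock genes, unfolded-protein-response genes, cholesterol synthesis genes, nuclear-encoded respiratory chain genes, cytosolic ribosomal protein genes, glutamate and GABA receptor genes, neuron markers, oligodendrocyte markers, oligodendrocyte precursor markers, astrocyte markers, microglia markers, endothelial markers, mural and fibroblast markers, choroid plexus markers, ependymal markers, pituitary markers, red blood cell transcripts, cerebellar granule and Purkinje cell markers, striatum and thalamus markers, Hox genes expressed in hindbrain and absent from forebrain and hypothalamus regional markers. Lists with 5 or more measured members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The fixed lists come from general knowledge, not from these samples. Genes were named by a fixed rule. The rule takes, per contrast, the 10 called genes with the largest rise and the 10 with the largest fall that had a mean of 50 or more in the higher group, groups that did not overlap and a symbol that is not provisional (no overlap rule for interactions). It adds up to 4 called members per list with the smallest p, and a panel of 13 genes whatever their p: Fkbp5, Per1, Sgk1, Tsc22d3, Fos, Nr4a1, Crh, Avp, Pomc, Nr3c1, Hmox1, Th and Dbh. With 5 or fewer calls all are named, and with none the 5 smallest p are named as not passing. Some genes of the rule are not reported here, most of them for length, and among the rest those whose call held when each library was left out were preferred, a preference added after the values were seen. Groups, contrasts, tests, lists, the naming rule and the alternatives listed next were set before the data were examined.

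The alternatives were pseudocounts of 0.5 and 5, no filter or a mean of 50, median-of-ratios rescaling, quantile normalization, limma sample weights, edgeR 4.0.16 quasi-likelihood tests and DESeq2 1.42.0 on the recovered reads, fits of the compared groups alone, the replicate number as a block for contrasts between tissues, and each library of the compared groups left out in turn. On the recovered reads edgeR called 134 genes for ozone in sham brainstem and 235 in sham hypothalamus. A list of 20 liver transcripts was written after the principal components had been seen and before it was tested. Another 3 alternatives were chosen after seeing the data, namely the liver list as a covariate, leaving out the 4 libraries with over 2000 liver-list reads per M reads (RPM), and leaving out brainstem ADREX ozone 81, which had 54.7 small RNA RPM. The limit of 2000 was also set after seeing the values.

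The pipeline was tested on simulated reads drawn from the real libraries' means with 200 genes changed by known folds. For ozone against air in sham brainstem (14408 genes) it recovered 17.9% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 92.4% of those changed 4-fold, with 5.7% of calls false. In the hypothalamus (14483 genes) the shares were 17.9%, 68.7% and 97%, with 3.2% false. For the interaction they were 3%, 32.8% and 75.8% in the brainstem and 16.4%, 47.8% and 89.4% in the hypothalamus. None of 29 random lists was called. Genes were drawn independently of each other, so these results do not cover correlation between genes, on which the list tests depend. Replicates were compared before averaging, and the 48 pairs of libraries within groups differed by a chi-square of 64.5 to 71.7 per degree of freedom in the 3 pairs with brainstem ADREX ozone 81 and of 2.78 to 31.6 in the others, well beyond sampling noise, so none was treated as a repeat of another.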

Results

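Gene expression was measured by mRNA sequencing in the brainstem and the hypothalamus of Wistar Kyoto rats, an inbred strain with normal blood pressure, at 13 weeks of age. The rats had undergone total bilateral adrenalectomy (ADREX), which removes the source of corticosterone and of circulating adrenaline, or a sham operation. They then breathed filtered air or ozone, an oxidant air pollutant, at 0.8 ppm for 4 hours, and tissue was collected immediately afterwards. The 2 tissues, 2 operations and 2 exposures made 8 groups of 4 libraries each, 32 in all. Libraries held 6.44 to 12.4 M reads, with 6.94 to 12.4 M in the brainstem and 6.44 to 9.11 M in the hypothalamus, and 17570 to 18584 genes had at least 1 read. Transcripts made by the liver, such as albumin, summed to between 17.5 and 4659 reads per M reads (RPM). They exceeded 2000 in 4 libraries, namely brainstem sham ozone 18, hypothalamus sham air 2, hypothalamus sham ozone 18 and hypothalamus ADREX air 68. Transthyretin (Ttr), a product of the choroid plexus, ranged from 11.6 to 5258 normalized counts over all libraries. Gabra6, a receptor subunit of cerebellar granule cells, ranged from 49.6 to 696.5 in the brainstem. Changes are given as log2 fold changes ± SE on the log2(value + 1) scale, with group levels as mean ± SD of normalized counts (n = 4 per group). The p-values measure the spread between these libraries, since nothing in the sources used here states that each came from a separate animal.

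**Figure D1:**
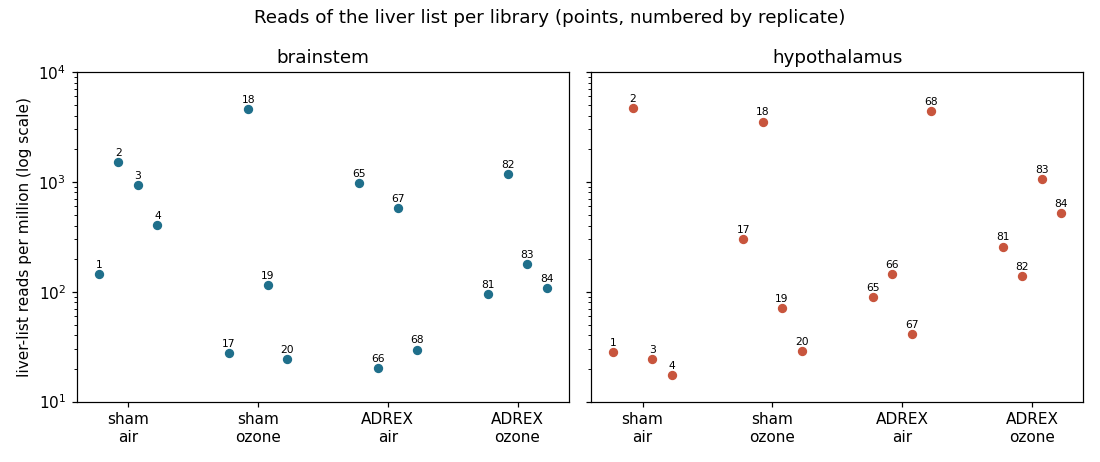
Reads of 20 liver transcripts per M reads (RPM; vertical axis, log scale) in each library, by group (horizontal axis). Points are libraries numbered by replicate, and the 4 libraries over 2000 RPM stood at 3534 to 4659, against at most 301 for the other libraries of their groups.

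The first comparison asked what ozone did to the brainstem of rats with intact adrenals. Genes known to respond to glucocorticoids led the change. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 2.31 ± 0.13, from 264 ± 33.9 normalized counts in air to 1308 ± 114 in ozone. The cell cycle inhibitor Cdkn1a (p21) rose by 2.82 ± 0.21, from 175 ± 35.2 to 1239 ± 189, and Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase, by 1.81 ± 0.13, from 1098 ± 119 to 3839 ± 209. Limma gave adjusted p = 6.14e-08, 4.93e-07 and 3.74e-07 for these 3 genes. Larger or similar changes from lower levels were seen for the hypoxia-inducible factor subunit Hif3a (3.41 ± 0.52), the zinc finger factor Zbtb16 (2.39 ± 0.36), the secreted phospholipase Pla2g3 (2.18 ± 0.19), the lipid droplet protein Plin4 (2.09 ± 0.36), the metallothioneins Mt1 (2.06 ± 0.32) and Mt2A (1.90 ± 0.25), the monooxygenase Fmo2 (2.02 ± 0.28) and the peroxisomal Pex11a (2.01 ± 0.14). Aspa, the oligodendrocyte enzyme that splits N-acetylaspartate, rose by 1.24 ± 0.17. Limma's adjusted p for these 9 genes lay between 3.74e-07 for Pex11a and 0.00726 for Plin4. Other genes fell. Rasgrp3, an exchange factor for Ras and Rap, had a change of -1.26 ± 0.09 (limma adjusted p = 3.74e-07), from 1584 ± 78.6 to 662 ± 60.7. The Toll-like receptor homologue Cd180 changed by -1.81 ± 0.26, the interferon-induced GTPase Gbp2 by -1.10 ± 0.20, the thyroid hormone transporter Slco1c1 by -1.04 ± 0.12, the secreted protease Adamts1 by -0.99 ± 0.18 and cyclin D1 (Ccnd1) by -0.94 ± 0.11, with limma adjusted p from 0.000105 for Slco1c1 to 0.00961 for Gbp2. In all, limma called 141 of 14408 genes, 84 higher and 57 lower, and 116 of them changed by 1.5-fold or more. The remaining genes of the fixed panel did not pass (Per1 0.72, Sgk1 1.24, Tsc22d3 0.40, Fos -0.66, Nr4a1 -0.19, Crh -0.11, Nr3c1 -0.45, Hmox1 -0.18, Th 0.17 and Dbh 0.04; limma adjusted p from 0.153 to 0.999). Left-out libraries changed 4 of those verdicts. Without sham ozone 18 limma gave adjusted p = 0.0352 for Per1 and 0.0363 for Sgk1 (over the alternatives 0.0307 to 0.464 and 0.013 to 0.738), and without ADREX ozone 81, a library of the fit outside the compared groups, 0.034 for Tsc22d3 and 0.00878 for Nr3c1 (0.034 to 1 and 0.00723 to 0.705). The count of calls was 90 without sham air 1, 93 without sham air 3, 75 without sham ozone 17, 79 without sham ozone 19 and 73 without sham ozone 20, and it was 272 without ADREX ozone 81.

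Among the fixed gene lists, the glucocorticoid-responsive genes rose together in the brainstem of sham rats after ozone. Of 36 measured members, 11 rose, none fell and 25 did not pass, while 18 rose when adjusted over the list alone. The median log2 change was 0.61, and 32 of the members had a positive change. Limma's camera gave adjusted p = 1.84e-31, and adjusted p = 0.00411 with an estimated correlation. The risen members included Fkbp5, Gpd1, Cdkn1a and Mt2A. Endothelial markers went the other way. Of 14 measured markers, 3 fell, namely Slco1c1, the angiopoietin co-receptor Tie1 (-0.69 ± 0.12) and the vascular endothelial growth factor receptor Kdr (-0.85 ± 0.18), and 7 fell when adjusted over the list alone. The median was -0.48, with camera adjusted p = 2.40e-12 and adjusted p = 0.0162 with an estimated correlation, both through limma. Kdr (limma adjusted p = 0.0257, 0.000813 to 0.122 over the alternatives) did not pass without any of sham air 1 (0.0956), 2 (0.0615), 3 (0.0654) or 4 (0.0698), sham ozone 17 (0.0644), 19 (0.115) or 20 (0.122). A further 4 lists passed camera's test at its preset correlation and lost the call with an estimated one. Interferon-responsive and antigen-presentation genes were lower (camera adjusted p = 5.68e-05 through limma; adjusted p = 0.245 with an estimated correlation), with Gbp2 as the 1 called member of 25 and 3 lower when adjusted over the list alone. Circadian clock genes were higher (camera adjusted p = 0.00108 through limma; 0.245 with an estimated correlation), with Usp2 as the 1 called member of 20 (1.19 ± 0.24; 4 higher when adjusted over the list alone). The call of Usp2 (limma adjusted p = 0.0156, 0.000427 to 0.0751 over the alternatives) was lost without sham air 3 (0.0654), sham ozone 17 (0.0561), sham ozone 19 (0.0751) or sham ozone 20 (0.0687). Nuclear-encoded respiratory chain genes (camera adjusted p = 0.0126 through limma, median 0.12) and cytosolic ribosomal protein genes (0.000527, median 0.22) were higher with no called member, and both had adjusted p = 0.778 with an estimated correlation. The other 23 lists (camera adjusted p from 0.091 to 0.934) did not pass, among them the immediate early genes, the NRF2 antioxidant genes and the inflammatory and acute-phase genes.

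**Figure D2:**
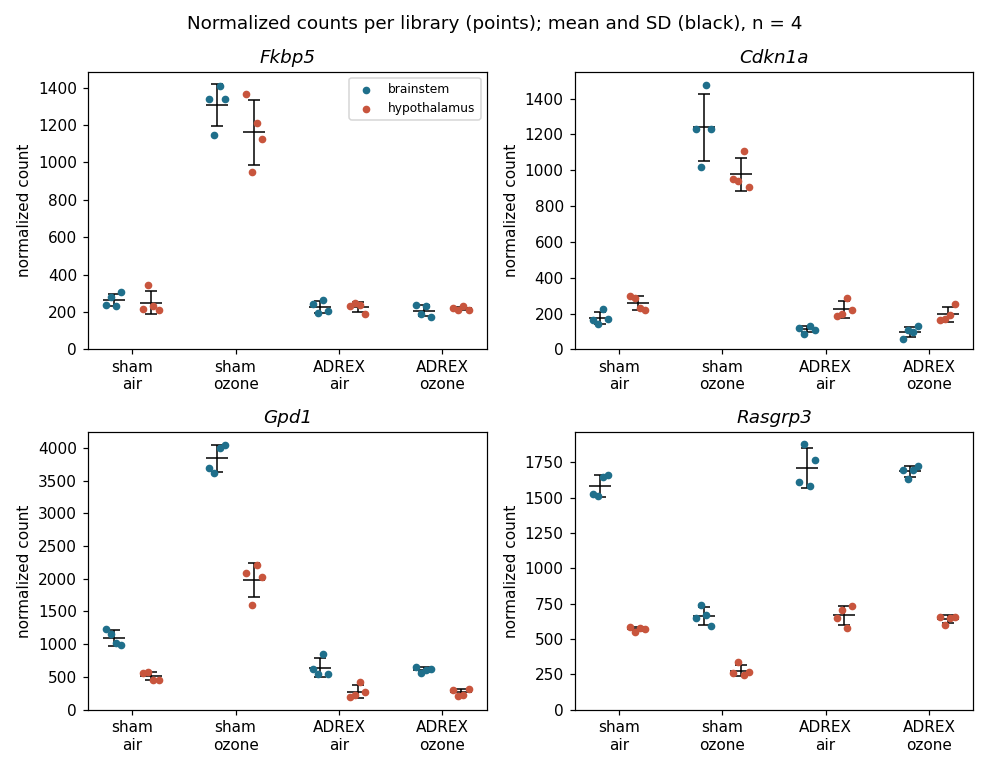
Normalized counts (vertical axis) of Fkbp5, Cdkn1a, Gpd1 and Rasgrp3 in each library of the 4 groups of each tissue (horizontal axis). Points are libraries and black marks are the group mean ± SD (n = 4). In the brainstem Fkbp5 averaged 1308 in sham ozone against 264 in sham air, 208 in ADREX ozone and 225 in ADREX air.

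The same question was put to the hypothalamus. Pla2g3 rose by 3.60 ± 0.29, from 27.7 ± 6.63 normalized counts in sham air to 342 ± 45.3 in sham ozone. Fkbp5 rose by 2.23 ± 0.14, from 249.9 ± 62.2 to 1162 ± 174, Gpd1 by 1.95 ± 0.20, from 511 ± 66.7 to 1981 ± 261, and Cdkn1a by 1.92 ± 0.16, from 259 ± 38.7 to 976 ± 91.2. Limma's adjusted p for these 4 genes ranged from 4.47e-07 for Fkbp5 to 4.11e-05 for Gpd1. Hif3a (3.15 ± 0.58), Plin4 (2.54 ± 0.33), Zbtb16 (2.10 ± 0.31), Trim72 (1.80 ± 0.28), a protein of membrane repair, and Aspa (1.5 ± 0.12) also rose, with limma adjusted p from 2.42e-06 to 0.00884. The glucocorticoid-induced leucine zipper Tsc22d3 rose by 0.62 ± 0.10 (limma adjusted p = 0.00454). Single members of other lists rose too, namely the oncostatin M receptor Osmr (1.38 ± 0.23), the small heat-shock protein Cryab (1.13 ± 0.11) and the sterol sensor Insig1 (0.61 ± 0.09), with limma adjusted p of 0.00388, 1.73e-05 and 0.00154. Falling genes included Rasgrp3 (-1.05 ± 0.10), Slco1c1 (-1.05 ± 0.12), Cd180 (-1.39 ± 0.20), Gbp2 (-1.07 ± 0.17), Elovl7 (-0.98 ± 0.13), an elongase of fatty acids, and Cml5 (-0.95 ± 0.18), with limma adjusted p from 1.08e-05 for Rasgrp3 to 0.0125 for Cml5. Limma called 230 of 14483 genes, 137 higher and 93 lower, and 143 changed by 1.5-fold or more. The other panel genes did not pass (Per1 0.60, Sgk1 1.13, Fos -0.89, Nr4a1 -0.25, Crh -0.20, Avp -0.21, Pomc -0.11, Nr3c1 -0.42, Hmox1 0.02 and Th 0.31; limma adjusted p from 0.133 to 0.978). Without sham ozone 18, Sgk1 (limma adjusted p = 0.0224) and Nr3c1, the glucocorticoid receptor (0.046), passed, and without sham ozone 19 Fos (0.0419) did. Over the alternatives their adjusted p ranged from 0.00692 to 0.351 for Sgk1, 0.00478 to 0.388 for Nr3c1 and 0.0344 to 0.362 for Fos. The count of calls was 120 without sham air 1, 124 without sham air 3, 129 without sham air 4, 115 without sham ozone 17 and 134 without sham ozone 20.

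Glucocorticoid-responsive genes were again the leading list in the hypothalamus of sham rats. Of 36 measured members, 13 rose and none fell, with 26 risen when adjusted over the list alone, and all 36 had a positive change (median 0.72). Limma's camera gave adjusted p = 1.34e-28, and adjusted p = 0.00695 with an estimated correlation. Endothelial markers were lower in 14 of 14 cases, of which 3 were called: Slco1c1, Kdr (-0.94 ± 0.16) and the sialomucin Emcn (-0.98 ± 0.17), with 6 lower when adjusted over the list alone. Their median was -0.36, with camera adjusted p = 2.04e-08 through limma, and the list missed the threshold at adjusted p = 0.0524 with an estimated correlation. Cholesterol synthesis genes were higher (camera adjusted p = 0.0348 through limma; adjusted p = 0.298 with an estimated correlation), and their 1 called member, Insig1, is a brake on synthesis and not an enzyme of it. The other lists did not pass camera's test at adjusted p from 0.0582 to 0.999 through limma. They were immediate early genes, neuropeptides and stress-axis genes, catecholamine synthesis, transport and receptors, HIF target genes, NRF2 antioxidant genes, inflammatory and acute-phase genes, interferon-responsive and antigen-presentation genes, circadian clock genes, heat-shock genes, unfolded-protein-response genes, nuclear-encoded respiratory chain genes, cytosolic ribosomal protein genes, glutamate and GABA receptor genes, neuron markers, oligodendrocyte markers, oligodendrocyte precursor markers, astrocyte markers, microglia markers, mural and fibroblast markers, choroid plexus markers, ependymal markers, pituitary markers, red blood cell transcripts, cerebellar granule and Purkinje cell markers, striatum and thalamus markers, hypothalamus regional markers. Oligodendrocyte markers moved both ways, with 2 higher, Aspa among them, and 2 lower of 19 (4 and 5 when adjusted over the list alone).

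Many genes were called in both tissues. Among 14077 genes tested in both, 52 rose in brainstem and hypothalamus of sham rats after ozone against 0.811 for independent lists, and 23 fell in both against 0.37, while none was called in opposite directions. The expected values take the tissues as independent, although the libraries carry the same numbers in both and the sources used here do not say whether a number marks a rat. Of the 140 brainstem calls also measured in the hypothalamus, 137 had the same sign there, and 223 of 229 hypothalamus calls had the same sign in the brainstem.

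After adrenalectomy, ozone changed no gene past the threshold in either tissue. In the brainstem Fkbp5 stood at 208 ± 30.3 normalized counts in ozone and 225 ± 32.9 in air (-0.12 ± 0.13), and in the hypothalamus at 219 ± 9.79 and 225 ± 25.2 (-0.04 ± 0.14). Limma called 0 of 14408 genes in the brainstem, where 851 had an unadjusted p under 0.05 against 720 expected by chance (426 without ADREX air 65, 1464 without ADREX ozone 82 and 392 with the compared groups alone), edgeR called 0 and DESeq2 called 1. In the hypothalamus limma called 0 of 14483, with 1163 at an unadjusted p under 0.05 against 724 expected by chance (501 without ADREX ozone 84, 735 without ADREX air 66, 1925 without ADREX ozone 82, 825 with the compared groups alone and 2083 without the libraries rich in liver transcripts), and edgeR and DESeq2 each called 0. The smallest p in the brainstem belonged to the provisional gene Rn50_14_0474.1 (1.75 ± 0.30, limma adjusted p = 0.358), which was also the gene DESeq2 called. Next came Yod1 (1.03), Slc1a5 (-0.60), LOC498675 (-0.95) and Sh3tc1 (0.60), each at limma adjusted p = 0.801. In the hypothalamus the 5 smallest were Nostrin (a 2.38-fold ratio, given without direction) and, as log2 changes, AC132760.1 (1.53), Ptgs1 (-0.64), Mief2 (0.47) and Ncoa5 (-0.38), all at limma adjusted p = 0.587. None of the panel passed in the brainstem (Fkbp5 -0.12, Per1 0.21, Sgk1 -0.39, Tsc22d3 -0.42, Fos -0.21, Nr4a1 -0.53, Crh -0.24, Nr3c1 0.02, Hmox1 -0.33, Th -0.08 and Dbh -0.24; limma adjusted p from 0.801 to 0.991) or in the hypothalamus (Fkbp5 -0.04, Per1 0.16, Sgk1 0.09, Tsc22d3 0.10, Fos -0.82, Nr4a1 -0.49, Crh -0.20, Avp 0.16, Pomc -0.41, Nr3c1 0.16, Hmox1 -0.17 and Th 0.05; limma adjusted p from 0.587 to 0.966). The genes called in sham rats had a median change, in the sham direction, of 0.00849 in the ADREX brainstem against 0.868 in sham, and of 0.108 in the ADREX hypothalamus against 0.685. These genes were picked by their sham change, which enlarges the sham medians and not the ADREX medians, so part of the gap comes from the choice. In ADREX rats 76 of 141 of them had the same sign as in sham in the brainstem, and 173 of 230 in the hypothalamus. Without ADREX ozone 81 the brainstem changes of several panel genes moved, to 0.016 for Tsc22d3, 0.023 for Sgk1, 0.12 for Crh, 0.24 for Nr3c1, -0.29 for Nr4a1, -0.22 for Hmox1, -0.18 for Fkbp5 and -0.03 for Th, still with no call.

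Of the gene lists, glucocorticoid-responsive genes did not pass in ADREX rats after ozone, with medians of -0.12 in the brainstem (camera adjusted p = 0.0522 through limma; the median was 0.005 without ADREX ozone 81) and -0.02 in the hypothalamus (0.728). Immediate early genes were lower in the brainstem in 25 of 30 cases (camera adjusted p = 2.66e-06 through limma; adjusted p = 0.248 with an estimated correlation), with no called member and 1 lower when adjusted over the list alone. No list test was repeated without ADREX ozone 81, so its part in this and the other brainstem shifts is not known. Cholesterol synthesis genes were higher in the hypothalamus, with 15 of 21 positive and 2 called when adjusted over the list alone (camera adjusted p = 0.000326 through limma; adjusted p = 0.0896 with an estimated correlation). Smaller shifts passed camera alone. In the brainstem these were neuropeptides and stress-axis genes, lower (0.654), unfolded-protein-response genes, lower (0.526), cholesterol synthesis genes, higher (0.526), choroid plexus markers, lower (0.656), cerebellar markers, higher (0.656), and striatum and thalamus markers, lower (0.526), where each number is limma's adjusted p with an estimated correlation. In the hypothalamus they were immediate early genes, lower (0.663), unfolded-protein-response genes, lower (0.673), respiratory chain genes, lower (0.869), and oligodendrocyte markers, higher (0.663), by the same limma adjusted p.

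**Figure D3:**
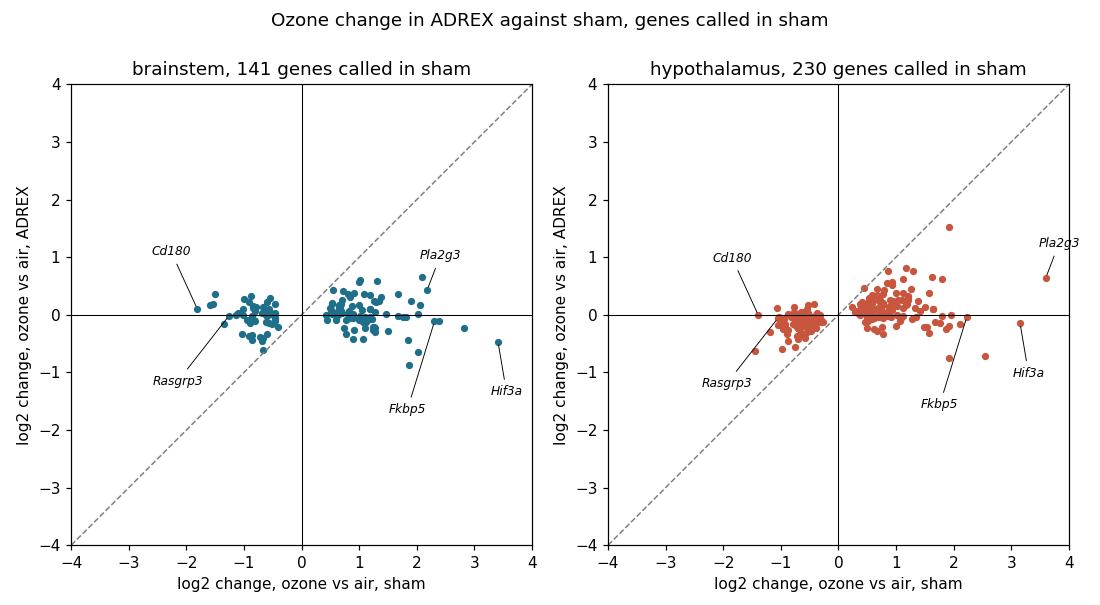
Log2 change after ozone against air in sham rats (horizontal axis) and in ADREX rats (vertical axis) for the 141 brainstem and 230 hypothalamus genes called in sham rats. Each point is a gene and the dashed line marks an equal change in both operations. The genes were picked by their sham change, which enlarges the sham values. In ADREX rats the brainstem points lie around 0, with a median in the sham direction of 0.00849, and the hypothalamus points lie slightly to the sham side, with a median of 0.108 and the same sign in 173 of 230.

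The effect of the operation itself was read from rats that breathed air. Sham-operated and ADREX brainstems differed in no gene past the threshold, and limma called 0 of 14408 genes (545 at an unadjusted p under 0.05, 720 expected by chance), edgeR 0 and DESeq2 16. The 5 smallest p-values were at Gpd1 (-0.79 ± 0.13), the Fc receptor-like Fcrl2 (1.09 ± 0.18) and Pla2g3 (-1.15 ± 0.19), each at limma adjusted p = 0.0539, and at the clock gene Per3 (0.70) and the lyase Etnppl (-1.06), each at 0.186. Single libraries decided 4 of these. Without ADREX air 67 limma gave adjusted p = 0.00139 for Gpd1, 0.00972 for Pla2g3 and 0.00273 for Etnppl, and 4 calls in all. Without ADREX ozone 81, which is outside the compared groups, it gave adjusted p = 0.0376 for Gpd1, 0.0376 for Fcrl2 and 0.0168 for Pla2g3, and 7 calls in all. Across alternatives the adjusted p of Gpd1 was 5.16e-05 to 0.49, of Pla2g3 5.16e-05 to 0.48, of Etnppl 0.00273 to 0.695 and of Fcrl2 0.000314 to 0.48. Panel genes did not pass (Fkbp5 -0.23, Per1 -0.62, Sgk1 -1.06, Tsc22d3 -0.15, Fos -0.17, Nr4a1 -0.08, Crh 0.10, Nr3c1 0.02, Hmox1 0.18, Th 0.14 and Dbh -0.27; limma adjusted p from 1 to 1). In the hypothalamus limma called 2 of 14483 genes (807 at an unadjusted p under 0.05, 724 expected by chance). Fcrl2 was higher after ADREX by 1.40 ± 0.21, at 189.9 ± 45.7 against 70.4 ± 11.4 normalized counts, and the matrix protein Sparc was lower by a log2 change of -0.44 ± 0.06, at 10058 ± 838 against 13595 ± 720.3 (limma adjusted p = 0.0278 for each). These calls were fragile. Fcrl2 was lost without any of sham air 1 (0.173), 2 (0.105), 3 (0.162) or 4 (0.117), ADREX air 66 (0.123) or 68 (0.104), and Sparc without any of sham air 1 (0.0989), 2 (0.135), 3 (0.212) or 4 (0.117), ADREX air 65 (0.179), 66 (0.123) or 67 (0.0505), as limma adjusted p (1.20e-06 to 0.203 and 3.09e-08 to 0.212 over the alternatives). The count was 0 without sham air 1, 2, 3 or 4 or ADREX air 66, 1 without ADREX air 65 or 68 and 7 without ADREX air 67. No panel gene passed (Fkbp5 -0.13, Per1 -0.32, Sgk1 -0.78, Tsc22d3 -0.12, Fos -0.23, Nr4a1 -0.01, Crh 0.27, Avp -0.21, Pomc -0.56, Nr3c1 0.03, Hmox1 0.54 and Th 0.06; limma adjusted p from 0.794 to 1).

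As a list, glucocorticoid-responsive genes lay lower in ADREX than in sham rats in air, with a median of -0.40 in the brainstem (camera adjusted p = 9.08e-11 through limma; adjusted p = 0.226 with an estimated correlation) and -0.20 in the hypothalamus (3.47e-05; adjusted p = 0.208 with an estimated correlation). None of its members passed over all genes, and 2 and 4 were lower when adjusted over the list alone. Astrocyte markers were lower in the hypothalamus, at a median of -0.20, and this call held at adjusted p = 0.0439 with an estimated correlation (camera adjusted p = 0.000543 through limma; 0 of 15 members called, 2 lower when adjusted over the list alone). The astrocyte list shares at least Gjb6 with the glucocorticoid-responsive genes, so these lists are not independent. Endothelial markers were higher in the brainstem (camera adjusted p = 0.00365 through limma; adjusted p = 0.409 with an estimated correlation) and in the hypothalamus (0.000487; adjusted p = 0.198 with an estimated correlation), with no called member. Mural and fibroblast markers were lower in the brainstem (adjusted p = 0.615 with an estimated correlation, through limma) and higher in the hypothalamus (0.142), and heat-shock genes were lower in the brainstem (0.375). In the hypothalamus, limma's adjusted p with an estimated correlation was 0.142 for oligodendrocyte markers, 0.198 for glutamate and GABA receptor genes, 0.198 for cholesterol synthesis genes, 0.337 for inflammatory genes, 0.678 for ribosomal protein genes and 0.711 for choroid plexus markers, each past camera's threshold only at its preset correlation.

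Among rats that breathed ozone, the brainstem of ADREX rats stood far from that of sham rats. This comparison uses the same sham ozone libraries as the comparison of ozone with air, so the 2 share the chance values of those libraries. Fkbp5 was lower by a log2 change of -2.66 ± 0.13, at 208 ± 30.3 against 1308 ± 114 normalized counts, Gpd1 by -2.65 ± 0.13, at 611 ± 32.8 against 3839 ± 209, and Cdkn1a by -3.69 ± 0.21, at 97.7 ± 29.2 against 1239 ± 189. Limma gave adjusted p = 3.21e-09, 2.91e-09 and 7.34e-09. Hif3a (-4.34 ± 0.52), the thiamine transporter Slc19a3 (-3.22 ± 0.31), Fmo2 (-2.99 ± 0.28), Zbtb16 (-2.95 ± 0.36), Pla2g3 (-2.90 ± 0.19), the kinase Sgk1 (-2.70 ± 0.42) and the clock gene Per1 (-1.14 ± 0.21) were lower as well, with limma adjusted p from 4.12e-08 for Pla2g3 to 0.0053 for Per1. Rasgrp3 was higher by 1.35 ± 0.09, at 1687 ± 38.1 against 662 ± 60.7 (limma adjusted p = 4.12e-08). Cd180 (1.69 ± 0.26), the macrophage receptor Adgre1 (1.35 ± 0.23), Rab7b (1.31 ± 0.17), Gbp2 (1.31 ± 0.20), Fcrl2 (1.28 ± 0.18), Adamts1 (1.28 ± 0.18) and Per3 (0.93 ± 0.13) were higher too, at limma adjusted p of 0.00267 for Adgre1, 0.00113 for Gbp2 and 0.000515 for Per3. Limma called 352 of 14408 genes, 172 higher and 180 lower, with 268 at 1.5-fold or more. Panel genes that did not pass were led by Tsc22d3 (Tsc22d3 -0.97, Fos 0.29, Nr4a1 -0.42, Crh -0.03, Nr3c1 0.49, Hmox1 0.03, Th -0.10 and Dbh -0.55; limma adjusted p from 0.0982 to 0.979). Without ADREX ozone 81 the changes were -0.53 for Tsc22d3, 0.71 for Nr3c1, 0.33 for Crh, -0.18 for Nr4a1, 0.14 for Hmox1 and -0.05 for Th, and Tsc22d3 (limma adjusted p = 0.00541) and Nr3c1 (0.000276) passed, against 0.00541 to 0.396 and 0.000137 to 0.479 over the alternatives. That library also enlarges the fall of Sgk1, which stood there at 81.59 normalized counts against 245.4 to 272.6 in the other ADREX ozone libraries. The count was 218 without sham ozone 17, 207 without sham ozone 19 and 197 without sham ozone 20.

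In the brainstem after ozone, 23 of 36 glucocorticoid-responsive genes were lower in ADREX than in sham rats and 13 did not pass, with 31 lower when adjusted over the list alone. Their median was -1.19 (camera adjusted p = 1.28e-45 through limma; adjusted p = 0.000725 with an estimated correlation), and members included Mt2A (-2.40) and the astrocyte connexin Gjb6 (-1.32). Endothelial markers were higher, 7 of 14 over all genes and 10 when adjusted over the list alone, including Kdr (1.07), Tie1 (0.97) and Slco1c1 (0.70). Limma's camera gave adjusted p = 9.28e-13 for them, and adjusted p = 0.0143 with an estimated correlation. Red blood cell transcripts had a median of -2.46, with no called member and 4 of 6 lower when adjusted over the list alone (camera adjusted p = 0.0027 through limma; adjusted p = 0.319 with an estimated correlation). Immediate early genes were lower with no called member (camera adjusted p = 0.00257 through limma; 0.31 with an estimated correlation). Interferon-responsive genes were higher (0.0027; adjusted p = 0.319 with an estimated correlation), with Gbp2 called and 2 higher when adjusted over the list alone, by limma's camera. Microglia markers were higher as a list (camera adjusted p = 0.0332 through limma; adjusted p = 0.193 with an estimated correlation), although Ctss, a microglial protease, was lower (-0.52) and Aif1 higher (0.82), with 5 higher and 1 lower when adjusted over the list alone. The call of Ctss was lost without sham ozone 17 (0.0745), sham ozone 18 (0.0707), sham ozone 19 (0.0506) or ADREX ozone 83 (0.0635) and that of Aif1 without any of sham ozone 17 (0.0886), 19 (0.0966) or 20 (0.118), ADREX ozone 81 (0.067) or 83 (0.0652), as limma adjusted p (0.00177 to 0.145 and 0.00399 to 0.118 over the alternatives). The other 23 lists (camera adjusted p from 0.0785 to 0.958) did not pass, through limma.

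The hypothalamus gave the matching comparison after ozone. Gpd1 was lower in ADREX by a log2 change of -2.90 ± 0.20, at 266 ± 52.1 against 1981 ± 261 normalized counts, Fkbp5 by -2.39 ± 0.14, at 219 ± 9.79 against 1162 ± 174, and Gpatch4 by -2.51 ± 0.15, at 92.4 ± 6.09 against 534 ± 81.4. Limma gave adjusted p = 1.81e-07, 6.13e-08 and 6.13e-08. Hif3a (-4.01 ± 0.58), Pla2g3 (-3.99 ± 0.29), Fmo2 (-3.01 ± 0.41), Slc19a3 (-2.96 ± 0.34), Plin4 (-2.93 ± 0.33), the matricellular growth factor Ctgf (-2.61 ± 0.28), Sgk1 (-1.82 ± 0.34) and Tsc22d3 (-0.65 ± 0.10) were lower too, with limma adjusted p from 3.83e-07 for Pla2g3 to 0.00698 for Sgk1 and 0.00209 for Tsc22d3. The pattern receptor Tlr2 was higher by 1.49 ± 0.21, Fcrl2 by 1.29 ± 0.21, Rasgrp3 by 1.21 ± 0.10, Cd180 by 1.20 ± 0.20, the tectorial membrane protein Tecta by 1.18 ± 0.15 and the cystine transporter Slc7a11 by 0.69 ± 0.12. For Tlr2, Rasgrp3 and Slc7a11 limma's adjusted p was 0.000711, 1.30e-06 and 0.00403. Nr3c1 was higher by 0.60 ± 0.13 (limma adjusted p = 0.0229, 0.000752 to 0.0916 over the alternatives), a call lost without any of sham ozone 17 (0.09), 19 (0.0916) or 20 (0.0715), ADREX ozone 83 (0.0625) or 84 (0.068). Limma called 325 of 14483 genes, 151 higher and 174 lower, with 211 at 1.5-fold or more. Panel genes that did not pass began with Per1 (Per1 -0.75, Fos -0.16, Nr4a1 -0.25, Crh 0.27, Avp 0.15, Pomc -0.86, Hmox1 0.35 and Th -0.20; limma adjusted p from 0.0823 to 0.898). Per1 passed without sham ozone 18 (limma adjusted p = 0.0129, 0.00794 to 0.283 over the alternatives). The count was 584 without sham ozone 18, a library rich in liver transcripts, 198 without sham ozone 19 and 204 without sham ozone 20.

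Of 36 glucocorticoid-responsive genes, 20 were lower in the ADREX hypothalamus after ozone and none was higher, with 27 lower when adjusted over the list alone (median -0.87; camera adjusted p = 1.19e-39 through limma and adjusted p = 0.0016 with an estimated correlation). Endothelial markers were higher in 8 of 14 cases, and in 10 when adjusted over the list alone, among them the vascular cadherin Cdh5 (0.87), Kdr (0.90) and Tie1 (0.77). The list had camera adjusted p = 6.62e-14 through limma, and adjusted p = 0.00787 with an estimated correlation. Oligodendrocyte markers were higher as a list, 7 higher and 2 lower of 19 (11 and 2 when adjusted over the list alone), with camera adjusted p = 3.69e-05 through limma and adjusted p = 0.0627 with an estimated correlation. Opalin, a myelin membrane protein, was higher by 0.96 ± 0.09, at 3027 ± 207 against 1559 ± 185 (limma adjusted p = 9.55e-06), and Fa2h, which hydroxylates myelin lipids, by 0.54 ± 0.08, while Aspa was lower (-1.18). Astrocyte markers were lower as a list (camera adjusted p = 0.0088 through limma; adjusted p = 0.0522 with an estimated correlation), with 1 higher and 2 lower over all genes and 1 and 5 when adjusted over the list alone. Its members Aldoc (-0.58), a glycolytic enzyme, and Gjb6 (-0.91), also on the glucocorticoid-responsive list, were lower. Interferon-responsive genes were higher (camera adjusted p = 0.0088 through limma; adjusted p = 0.471 with an estimated correlation), with Gbp2 (1.03) as the 1 called member. The other 24 lists (camera adjusted p from 0.069 to 0.974) did not pass, through limma.

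Whether ozone acted differently in ADREX and sham rats was tested directly as the interaction of exposure and operation, which uses all 4 groups of a tissue. In the brainstem the change after ozone was lower in ADREX than in sham rats by -3.06 ± 0.29 for Cdkn1a, -2.42 ± 0.19 for Fkbp5, -2.0 ± 0.20 for Pex11a and -1.86 ± 0.18 for Gpd1, on the log2 scale. Limma gave adjusted p = 3.12e-05, 6.34e-06, 4.19e-05 and 3.12e-05. Slc19a3 (-2.75), Fmo2 (-2.66), Tnfrsf11a (-1.81), Pcdh20 (-1.78), Pla2g3 (-1.75) and Aspa (-1.51) had negative interactions as well, with Rasgrp3 positive at 1.24 ± 0.12 (limma adjusted p = 3.70e-05). In the hypothalamus the interactions were -3.25 ± 0.47 for Plin4, -2.96 ± 0.41 for Pla2g3, -2.26 ± 0.20 for Fkbp5, -2.12 ± 0.22 for Cdkn1a, -1.96 ± 0.28 for Gpd1 and -1.92 ± 0.21 for Gpatch4, with limma adjusted p from 6.54e-05 for Fkbp5 to 0.00407 for Gpd1, and Rasgrp3 was positive at 0.99 ± 0.14 (limma adjusted p = 0.00305). Limma called 29 genes in the brainstem, 7 positive and 22 negative, and 20 in the hypothalamus, 3 positive and 17 negative. Panel genes without a call had interactions in the brainstem of Per1 -0.52, Sgk1 -1.63, Tsc22d3 -0.82, Fos 0.45, Nr4a1 -0.34, Crh -0.13, Nr3c1 0.47, Hmox1 -0.15, Th -0.24 and Dbh -0.28; limma adjusted p from 0.678 to 0.997. In the hypothalamus they were Per1 -0.43, Sgk1 -1.04, Tsc22d3 -0.52, Fos 0.07, Nr4a1 -0.25, Crh -0.01, Avp 0.36, Pomc -0.30, Nr3c1 0.57, Hmox1 -0.19 and Th -0.26; limma adjusted p from 0.384 to 1. Without ADREX ozone 81 the brainstem interactions were -0.39 for Tsc22d3, 0.23 for Crh, -0.10 for Nr4a1 and -0.04 for Hmox1, with no call, and Nr3c1 passed at 0.69 (limma adjusted p = 0.0196, 0.0196 to 1 over the alternatives). The brainstem interaction of Sgk1 is also enlarged by that library, at 81.59 normalized counts against 245.4 to 272.6 in the others of its group. The brainstem count was 18 without sham air 4, sham ozone 17, sham ozone 20 or ADREX air 68, 19 without sham ozone 19, ADREX air 65 or ADREX ozone 83, and 47 without ADREX ozone 81, and the hypothalamus count was 37 without sham ozone 18.

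Glucocorticoid-responsive genes had negative interactions as a list. In the brainstem 34 of 36 members were negative and 4 were called (18 when adjusted over the list alone; median -0.98), and in the hypothalamus 35 were negative and 4 called (15 when adjusted over the list alone; median -0.85). Limma's camera gave adjusted p = 9.78e-31 and 1.53e-33, and adjusted p = 0.00456 and 0.00344 with an estimated correlation. The size of the medians depended on the setting. In the brainstem the median was -0.679 without ADREX ozone 81 and -1.075 without the liver-rich libraries. In the hypothalamus it was -0.685 with the liver covariate, -0.696 with quantile normalization and -0.842 without the liver-rich libraries. Endothelial markers had positive interactions, with medians of 0.38 and 0.38, no called member, and 3 and 2 called when adjusted over the list alone. Their camera adjusted p was 1.02e-06 in the brainstem and 1.98e-07 in the hypothalamus through limma, but adjusted p = 0.131 and 0.0794 with an estimated correlation, so the difference between operations did not pass there. In the brainstem, immediate early, interferon-responsive, cholesterol synthesis and respiratory chain genes passed camera alone (limma adjusted p = 0.64 with an estimated correlation for each), and in the hypothalamus mural and fibroblast markers did (0.854 with an estimated correlation).

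The hypothalamus and the brainstem of sham rats in air differed in 4509 of 14533 genes by limma, 2319 higher in the hypothalamus and 2190 lower. Pmch, the precursor of melanin-concentrating hormone, stood at 2952 normalized counts in the hypothalamus and 14.3 in the brainstem (7.94 ± 0.72), vasopressin (Avp) at 429 and 2.49 (7.13 ± 0.59) and oxytocin (Oxt) at 377 and 2.06 (6.92 ± 0.55). The transcription factors Sim1 (6.47), Fezf1 (6.40), Dlx1 (6.28) and Nkx2-1 (6.11), histidine decarboxylase Hdc (5.47) and orexin Hcrt (4.35) were higher in the hypothalamus too. The serotonin transporter Slc6a4 stood at 1.47 in the hypothalamus against 469 in the brainstem (-7.52 ± 0.36), the noradrenaline transporter Slc6a2 at 0.235 against 168 and Dbh, which makes noradrenaline, at 0.685 against 182 (-6.88 ± 0.47). Limma's adjusted p was 4.58e-10 for Pmch, 7.52e-11 for Avp, 8.40e-16 for Slc6a4 and 1.11e-12 for Dbh. Hoxb5, at 508 normalized counts in the brainstem, and Hoxa5, at 189, were listed at 0 in all 4 hypothalamus libraries. Of the panel, Pomc was higher in the hypothalamus (4.70) and Crh lower (-1.21 ± 0.28; limma adjusted p = 0.00131). Fos (0.69) and Th (0.85) were higher and Tsc22d3 (-0.67) lower at limma adjusted p of 0.0342, 0.0249 and 0.0224, and over the alternatives these ranged from 0.0038 to 0.129, 0.000936 to 0.0734 and 3.95e-06 to 0.0742. Fos was lost without any of brainstem sham air 2 (0.066), 3 (0.129) or 4 (0.0532), hypothalamus sham air 1 (0.105), 3 (0.109) or 4 (0.0633), Th without brainstem sham air 2 (0.0592), brainstem sham air 4 (0.0527), hypothalamus sham air 1 (0.0734) or hypothalamus sham air 4 (0.0677) and Tsc22d3 without hypothalamus sham air 3 (0.0742). The other panel genes did not pass (Fkbp5 -0.10, Per1 0.33, Sgk1 -0.29, Nr4a1 0.57, Nr3c1 0.18 and Hmox1 -0.39; limma adjusted p from 0.0938 to 0.645). With the replicate number as a block, 4118 genes were called and Per1 passed (limma adjusted p = 0.0411, 0.0411 to 0.629 over the alternatives).

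Oligodendrocyte markers were lower in the hypothalamus in all 19 cases, among them Ugt8 (-1.72), over all genes and when adjusted over the list alone. All 10 Hox genes of the hindbrain were lower. Of 12 hypothalamus regional markers, 9 were higher and 1 lower. Limma's adjusted p with an estimated correlation was 0.000205 for oligodendrocyte markers, 0.000598 for Hox genes and 0.00298 for the regional markers. Cholesterol synthesis genes were lower in 17 of 21 cases (18 when adjusted over the list alone) at limma adjusted p = 0.00865 with an estimated correlation. Glutamate and GABA receptor genes were mostly higher, 27 up and 6 down of 40 (29 and 6 when adjusted over the list alone; limma adjusted p = 0.0378 with an estimated correlation), with Gabra4 (3.43) up and the glycine receptor Glra1 (-2.80) down. Oligodendrocyte precursor markers were lower in 5 of 8 cases (0.0327) and astrocyte markers in 6 of 15 with 1 higher (0.0152; Gfap -1.60), and pituitary markers were higher in 4 of 6 (0.0152) and striatum and thalamus markers in 7 of 13 with 1 lower (0.0352; Prkcd 3.69), each number being limma's adjusted p with an estimated correlation. Lists that passed camera and not the test with an estimated correlation were neuropeptides and stress-axis genes (13 up, 5 down; 0.1), circadian clock genes (11 up; 0.0503), ependymal markers (6 up, 1 down; 0.0567), endothelial markers (6 down; 0.119), mural and fibroblast markers (9 down; 0.119), interferon-responsive genes (8 down; 0.224), heat-shock genes (6 down, 1 up; 0.164) and respiratory chain genes (7 down; 0.518), by the same limma adjusted p. The other 13 lists (camera adjusted p from 0.0672 to 0.936) did not pass. Neuron markers, for example, moved both ways, with the neurofilament Nefl lower (-1.79) and synaptotagmin Syt1 higher (1.65).

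Whether ozone acted differently in the 2 tissues was tested as an interaction of exposure and tissue. Limma called 0 of 14533 genes in sham rats (416 at an unadjusted p under 0.05, 727 expected by chance, with 221 without brainstem sham air 3 and 677 without hypothalamus sham ozone 19), edgeR 0 and DESeq2 2. In ADREX rats limma called 0 (725 at an unadjusted p under 0.05, 727 expected by chance, with 334 without hypothalamus ADREX ozone 84 and 1327 without brainstem ADREX ozone 83), and edgeR and DESeq2 each 0. The smallest p-values in sham rats belonged to Pla2g3 (1.42 ± 0.35), Mapkapk3 (0.57), Csf1 (0.48), Smim5 (1.21) and Pex11a (-0.67), all at limma adjusted p = 0.983. Pla2g3 passed at limma adjusted p = 0.026 when only the 4 sham groups were fitted (0.00651 to 1 over the alternatives). In ADREX rats they belonged to Hist1h2bk (-1.45), Dusp16 (-0.76), Metrnl (1.02), Map3k15 (-1.85) and Yod1 (-1.20), all at limma adjusted p = 0.774. No panel gene passed in sham (Fkbp5 -0.08, Per1 -0.13, Sgk1 -0.11, Tsc22d3 0.22, Fos -0.23, Nr4a1 -0.06, Crh -0.09, Avp -0.68, Pomc -0.27, Nr3c1 0.03, Hmox1 0.20, Th 0.14 and Dbh 1.33; limma adjusted p from 0.983 to 0.998) or ADREX rats (Fkbp5 0.08, Per1 -0.04, Sgk1 0.48, Tsc22d3 0.52, Fos -0.61, Nr4a1 0.04, Crh 0.04, Avp 0.45, Pomc -0.49, Nr3c1 0.14, Hmox1 0.16, Th 0.13 and Dbh 0.55; limma adjusted p from 0.774 to 0.987). In sham rats 5 lists passed camera and not the test with an estimated correlation, namely Hox genes (0.409), respiratory chain genes (0.958), ribosomal protein genes (0.958), mural and fibroblast markers (0.863) and cholesterol synthesis genes (0.863), given as limma's adjusted p with that correlation, and in ADREX rats no list passed.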

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

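The tests of depth and of the liver list over the study's groups were written beforehand, and those of the liver covariate, the adrenals, the endothelial and vessel shares, liver RNA carried into libraries, a single liver source, other splits and reordered residuals after the result they bear on had been seen.

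The change after ozone differed between ADREX and sham rats in 29 brainstem and 20 hypothalamus genes, by limma's test of the interaction. Positive interactions in the brainstem were Cd180 1.92, Adamts1 1.27, Rasgrp3 1.24, Ccnd1 0.85, Pak7 0.85 and Rffl 0.81. Negative ones were Hif3a -3.88, Cdkn1a -3.06, Slc19a3 -2.75, Fmo2 -2.66, Fkbp5 -2.42, Pex11a -2.0, Gpd1 -1.86, Tnfrsf11a -1.81, Pcdh20 -1.78, Pla2g3 -1.75 and Aspa -1.51. In the hypothalamus the positive ones were Rasgrp3 0.99, Opalin 0.71 and Ccnd1 0.71. The negative ones were Plin4 -3.25, Pla2g3 -2.96, Fkbp5 -2.26, Cdkn1a -2.12, Gpd1 -1.96, Gpatch4 -1.92, Tnfrsf11a -1.83, Pnpla2 -1.75, Pex11a -1.38 and Aspa -1.37. Pnpla2, a triglyceride lipase, has a near copy in the gene table, so its value is uncertain. Single libraries decided several of these calls by limma's adjusted p. Cd180 in the brainstem was lost without any of sham air 1 (0.0755), 2 (0.102), 3 (0.102) or 4 (0.0823), sham ozone 17 (0.0899), 19 (0.113) or 20 (0.107), ADREX air 65 (0.0964), 66 (0.0604), 67 (0.112) or 68 (0.103), ADREX ozone 82 (0.0898), 83 (0.105) or 84 (0.114), with 0.000299 to 0.114 over the alternatives. Adamts1 in the brainstem was lost without any of sham air 1 (0.0775), 2 (0.0942), 3 (0.108) or 4 (0.105), sham ozone 17 (0.124), 19 (0.127) or 20 (0.107), ADREX air 65 (0.109), 66 (0.0536), 67 (0.0551) or 68 (0.121), ADREX ozone 81 (0.0554), 82 (0.0755), 83 (0.118) or 84 (0.0725), with 0.004 to 0.127 over the alternatives. Pak7 in the brainstem was lost without any of sham air 1 (0.0501), 2 (0.0578) or 4 (0.0535), sham ozone 20 (0.0722), ADREX air 65 (0.0516) or 68 (0.0605), with 4.27e-05 to 0.0722 over the alternatives. Hif3a in the brainstem was lost without any of sham air 1 (0.0943), 3 (0.0937) or 4 (0.0614), sham ozone 17 (0.105), 19 (0.127) or 20 (0.12), ADREX air 65 (0.101), 66 (0.0536) or 67 (0.103), ADREX ozone 82 (0.0755), 83 (0.105) or 84 (0.0673), with 0.000769 to 0.127 over the alternatives. Rffl in the brainstem was lost without any of sham air 2 (0.064), 3 (0.0682) or 4 (0.0571), sham ozone 17 (0.0695), 19 (0.0655) or 20 (0.0771), ADREX air 65 (0.0516) or 68 (0.0582), ADREX ozone 83 (0.0712) or 84 (0.0673), with 5.68e-05 to 0.0771 over the alternatives. Ccnd1 in the brainstem was lost without any of sham air 3 (0.0599) or 4 (0.0571), sham ozone 17 (0.0667) or 20 (0.0762), ADREX air 66 (0.0536), 67 (0.0636) or 68 (0.061), ADREX ozone 83 (0.0706), with 7.96e-05 to 0.0762 over the alternatives. Opalin in the hypothalamus was lost without any of sham air 1 (0.053), 2 (0.0667) or 4 (0.0859), sham ozone 19 (0.0694) or 20 (0.0751), ADREX air 66 (0.0508) or 68 (0.0568), ADREX ozone 81 (0.0756) or 83 (0.0582), with 7.23e-05 to 0.0859 over the alternatives. Ccnd1 in the hypothalamus was lost without any of sham air 1 (0.0626), 2 (0.0649) or 4 (0.0707), sham ozone 17 (0.0694) or 19 (0.0694), ADREX air 66 (0.0508), 67 (0.0668) or 68 (0.0503), ADREX ozone 81 (0.0735) or 83 (0.0659), with 0.000166 to 0.0997 over the alternatives. Tnfrsf11a in the hypothalamus was lost without any of sham air 1 (0.0626), 3 (0.0748) or 4 (0.0637), sham ozone 17 (0.0769), 19 (0.0694) or 20 (0.0751), ADREX ozone 82 (0.0515) or 83 (0.0546), with 3.87e-05 to 0.0769 over the alternatives.

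The pattern a biologist would follow first is the rise of glucocorticoid-responsive genes in sham rats after ozone, with list medians of 0.606 in the brainstem and 0.722 in the hypothalamus. Liver RNA in some libraries is argued against as its source, because the medians with the liver list as a covariate were 0.657 and 0.671. With all libraries thinned to 6.44 M reads, as a test of sequencing depth, the medians were 0.659 and 0.733. Thinning keeps the expected ratios between libraries, so it cannot decide about depth. Total reads of sham air and sham ozone overlapped, at 7.50 to 8.63 and 6.94 to 11.3 M in the brainstem. In the hypothalamus they were 6.48 to 8.75 and 7.78 to 8.55 M. A response that needs the adrenals is consistent with the interaction of the list, where limma's camera with an estimated correlation gave adjusted p = 0.00456 in the brainstem and 0.00344 in the hypothalamus. Corticosterone released during exposure is thus a candidate explanation, but no hormone was measured here, adrenaline is lost with the adrenals too, and the pattern remains a hypothesis.

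Endothelial markers were lower after ozone in sham rats, with medians of -0.48 in the brainstem and -0.36 in the hypothalamus, where the list missed the threshold of limma's camera with an estimated correlation (adjusted p = 0.0524). A lower share of endothelial cells alone would lower markers made only in those cells by about the same amount. The changes had a heterogeneity of 49.5 in the brainstem and 63.9 in the hypothalamus. Only the real split, 1 of 35 in the brainstem and 1 of 35 in the hypothalamus, was that uneven (highest other 22.3 and 30.5). Other splits put the ozone change into the spread between libraries, which lowers their heterogeneity. Markers also made in other cells would fall unequally, so the test cannot decide and a lower share stays open. Less vessel tissue in the sample would lower mural and fibroblast markers too, and their median of 0.146 in the hypothalamus (quartiles 0.064 to 0.355) argues against it there. In the brainstem their median of -0.164 (quartiles -0.298 to -0.025) leaves less vessel tissue open, since it lies between no change and the endothelial change. A change of regulation within endothelial cells may also remain in both tissues and was not tested.

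Liver transcripts stood far from the rest of the group in brainstem sham ozone 18 at 4577 RPM, hypothalamus sham air 2 at 4659, hypothalamus sham ozone 18 at 3534, hypothalamus ADREX air 68 at 4380 and brainstem ADREX ozone 82 at 1178. In the 4 richest, albumin alone held between 11963 and 18812 reads, and of the 20 listed genes 14 had a median of 10 or more normalized counts in the other 28 libraries, while the fixed lists held 0 of them. Liver RNA carried into some libraries is a candidate source. The listed genes rose together across libraries with median rank correlations of 0.944 in the brainstem and 0.952 in the hypothalamus. The list was written after the principal components of these libraries had been seen, so the correlations are no separate test of the source. The other libraries in the groups of the 4 richest held 24.4 to 115, 17.5 to 28.1, 28.8 to 301 and 41.4 to 145 RPM. The highest values were thus not shared within a group. That comparison was added after the permutation p-values over the 4 groups, 0.658 and 0.781, had been seen. A smaller difference between the study's groups stays open, since neither check excludes it. Hypothalamus ADREX ozone libraries held 139.6 to 1061 RPM, and brainstem sham air libraries 144.7 to 1519. Whether the 4 libraries share a single liver source stays open, as the ratio of Bhmt to Ahsg reads was 0.085 and 0.092 in the libraries numbered 18 and 0.441 and 0.706 in the others, but their chi-square of 275 per degree of freedom covers counting error only.

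Other splits of the same libraries tested whether chance can account for each count of calls. For ozone in sham rats the real split gave 141 calls in the brainstem and 230 in the hypothalamus. The highest other split gave 0 in each, so 1 of 35 splits was as large in both. This is the smallest share that 35 splits can give. Chance is unlikely there but not excluded, and no correction was made for the number of contrasts. A real count of 0 is reached by every split, so the splits say nothing about ozone in ADREX rats in the brainstem (35 of 35, highest other 1) or the hypothalamus (35 of 35, highest other 0), ADREX against sham in brainstem air (35 of 35, highest other 5), or ozone by tissue in sham (100 of 100, highest other 140) and ADREX rats (100 of 100, highest other 19). For ADREX against sham in air, 1 of 35 reached the hypothalamus count of 2 (highest other 0), but the count was 0 with no filter, with the compared groups alone, without the liver-rich libraries and without sham air 1, 2, 3 or 4 or ADREX air 66, so chance stays open for so small a count. In ozone, 1 of 35 reached the brainstem count of 352 (highest other 0), so chance is unlikely there too. In the hypothalamus 2 of 35 reached 325, because the split that set ADREX ozone 81, 83 and 84 with sham ozone 18 against the rest called 1477 genes, so chance is not excluded by this count, and so high a count points to a structure of the samples. Among 100 drawn splits for the interaction, 2 reached the brainstem count of 29 (highest other 39) and 4 the hypothalamus count of 20 (highest other 115). The splits with 39 and 115 calls kept sham ozone 17 to 20 together and mixed the ADREX libraries, and most other splits broke up the ozone change of sham rats, so these shares do not bear on the interaction alone. With both main effects kept and the residuals of the fit without interaction reordered, 1 of 100 orders reached 29 in the brainstem (highest other 5). In the hypothalamus 4 of 100 reached 20 (highest other 285). Chance is therefore unlikely in the brainstem and stays open in the hypothalamus, where 100 orders cannot place the share under 0.05. Between tissues 1 of 35 splits reached 4509 calls (highest other 1), which makes chance unlikely.

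Single libraries stood apart from the other 3 of their group, in 17 of 116 groups of values tested, where chance would give about 5.8 at the critical value of 0.829 if values were normally distributed. The values were not log-transformed, and the 17 include the liver list, written after the principal components had been seen. The excess over 5.8 is therefore no test of chance. Total reads were 11.33 M in brainstem sham ozone 18 and 9.825 M in brainstem ADREX air 66. Small RNA reads were at 3651 RPM in hypothalamus ADREX ozone 84. Brainstem ADREX ozone 81 was the lowest of its group for Sgk1 at 81.59 normalized counts, Tsc22d3 at 576.7 and Crh at 19.93. Tsc22d3 stood at 2456 in hypothalamus sham ozone 17, Fos at 76.21 in brainstem ADREX air 65, Crh at 34 in hypothalamus ADREX ozone 84, Nr3c1 at 994.2 in brainstem sham air 1, Hmox1 at 27.42 in hypothalamus sham ozone 20 and Th at 125.9 in brainstem ADREX air 66.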

How the results depend on the processing

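The alternatives with the liver covariate, without the libraries rich in liver transcripts and without brainstem ADREX ozone 81 were chosen after seeing the data, and the tests of all other settings beforehand. No named gene reversed its direction with a call under any setting. Of 458 gene values, 457 stayed on their side of the threshold with a pseudocount of 0.5 or of 5, 438 with no filter, 458 with median-of-ratios rescaling, 451 with quantile normalization, 440 with sample weights, 448 with edgeR and 448 with the liver covariate. It was 397 of 399 with a filter at a mean of 50, 446 of 457 with DESeq2, 438 of 457 without the liver-rich libraries, 370 of 406 with the compared groups alone and 291 of 303 without brainstem ADREX ozone 81. Over 4360 values with a library left out, 323 lost and 12 gained a call. The cause was not tested for any of the changes below.

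With limma's sample weights the counts were 496 for ozone in sham brainstem (141 in the main setting), 7 for ADREX against sham in brainstem air (0), 760 in brainstem ozone (352) and 94 for the brainstem interaction (29), and in the hypothalamus 886 (230), 4 (2), 1011 (325) and 90 (20). With these weights 237 were higher and 259 lower for ozone in sham brainstem (84 and 57 in the main setting), 439 and 447 in sham hypothalamus (137 and 93), 401 and 359 for ADREX against sham in brainstem ozone (172 and 180) and 533 and 478 in hypothalamus ozone (151 and 174), so the majority changed sides in all 4. DESeq2 called 237 genes for ozone in sham brainstem, 1 for ozone in ADREX brainstem (0), 16 for ADREX against sham in brainstem air and 75 for the brainstem interaction, and in the hypothalamus 412 for ozone in sham, 15 for ADREX against sham in air and 53 for the interaction. For ozone by tissue in sham rats it called 2 (0). It gave no adjusted p for up to 2604 genes of a contrast, which were left out of its counts. With the compared groups alone the count was 148 for ADREX against sham in brainstem ozone, 161 in hypothalamus ozone, 0 in hypothalamus air and 1 for ozone by tissue in sham rats, fits with fewer libraries, and the higher and lower genes in ozone were 50 and 98 in the brainstem and 53 and 108 in the hypothalamus. With no filter 0 genes were called for ADREX against sham in hypothalamus air and 1 for ozone by tissue in ADREX rats. Quantile normalization left 1 of the 2 calls for ADREX against sham in hypothalamus air, 1 higher and 0 lower against 1 and 1. Without brainstem ADREX ozone 81 the counts were 272 for ozone in sham brainstem, 7 for ADREX against sham in air and 47 for the interaction. It was the only library left out singly from contrasts that do not compare its group. Without the liver-rich libraries they were 0 for ADREX against sham in hypothalamus air, 591 in hypothalamus ozone and 32 for the hypothalamus interaction. Of 77 list calls by camera, 19 held with an estimated correlation, and fry called 39, of which 32 were among the 77. Fry, which does not compare a list with other genes, also called a few lists that camera did not.

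Leaving out each library of the compared groups in turn gave 73 to 157 calls for ozone in sham brainstem, 0 to 0 in ADREX brainstem, 0 to 4 for ADREX against sham in brainstem air, 197 to 444 in brainstem ozone and 18 to 47 for the brainstem interaction. In the hypothalamus the ranges were 115 to 220, 0 to 0, 0 to 7, 198 to 584 and 15 to 37, and between tissues 3866 to 4314, then 0 to 0 for ozone by tissue in sham and 0 to 0 in ADREX rats. No called gene of any contrast reversed its sign in these fits.

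The replicate numbers shared by the tissues were checked as pairs. The deviations of same-numbered libraries from their group means correlated by -0.531 to 0.612 over the 16 numbers, with 7 over 0.1, and 4 of 16 libraries correlated best with their own number, as chance gives (4). So this check found no pairing over all genes, but it does not exclude that a number marks an animal. The replicate block gave 4118 calls between tissues against 4509, 4010 of them among the 4509, and 0 and 0 for ozone by tissue, and among named genes it changed only Per1, which passed.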

Other observations

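The test of the haemoglobin pattern below was chosen after the pattern had been seen, and the values of neighbouring tissue and of the other transcripts were not tested.

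Transcripts of neighbouring tissue varied between libraries of the same group. Gabra6, which marks cerebellar granule cells, ranged from 49.6 to 696.5 normalized counts over the 16 brainstem libraries and from 0 to 7.61 over the 16 hypothalamus libraries. Transthyretin (Ttr), which the choroid plexus makes in bulk, ranged from 11.6 to 1753 in the brainstem and from 16.3 to 5258 in the hypothalamus. Within sham air brainstem alone, Gabra6 spanned 49.6 to 420.8 and Ttr 17.2 to 1753.

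The haemoglobin transcript Hbb varied between libraries in a way that followed the replicate number. Over the 16 numbers, the deviation of Hbb from its group mean in the brainstem correlated with that in the hypothalamus at r = 0.982 (permutation p = 3e-05) and rho = 0.974 (permutation p = 0.00011), from 100000 two-sided permutations whose smallest possible p is 1e-05. Without the numbers 81 and 68, farthest from the median, r was 0.968 (permutation p = 0.00046). A shared number may therefore mark 1 animal whose blood reached both samples. This hypothesis was noticed and tested on the same data. The check over all genes neither bore it out nor excluded it. A batch of animals handled together by number was not tested, and Hbb was the only transcript tested this way. Other values by number went both ways. The pituitary transcript Gh1 had 39 reads in brainstem and 33 in hypothalamus library 19, but 10 and 0 in those numbered 83, and 0 to 2 in all others. Libraries numbered 18 were rich in liver transcripts in both tissues, with a correlation of 0.612 over all genes, and that numbered 2, rich in the hypothalamus, had 1519 RPM in the brainstem (correlation 0.258), while number 68, rich in the hypothalamus, had 29.7 RPM in the brainstem (-0.531).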
